A study of Rattus norvegicus with 18 samples.

How the data were processed

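The data set holds 18 Illumina rat BeadArray profiles, 1 array per pup, from total brain and frontal lobe of female Wistar rats whose dams received vehicle or BDE-47 at 0.002 or 0.2 mg/kg per injection, with 3 pups of different litters in each of 6 groups. Per the labels, RNA was purified on columns, and biotin-labelled cRNA was hybridized. The deposited values are on a log2-like scale after normalization by the authors with lumi, per the submitters' processing notes. The version of lumi, the background correction, the transformation (log2 or lumi's variance stabilization, which approaches log2 at high signal) and the normalization method are not given in the sources used here. Differences are therefore called log2 differences, with the reservation that near the floor a variance-stabilized scale would compress them. The values run from 7.45 to 15.75 with a median of 7.86 and carry no detection p values. Array medians show that the tissues seem to have been normalized separately. No chip or batch is named in the labels.

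The deposited values were used without a further transformation or filter. Of 22523 probes, 13793 carried 1 gene symbol in the platform annotation, for 13337 distinct symbols, and 8730 carried none. The gene reference used here belongs to another genome build than the array annotation and served only for names, matching 13752 probes by Entrez identifier.

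Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default prior), and figures were drawn in Python 3.11.15. Dose contrasts were fitted within each tissue on its 9 arrays, and the interactions and the contrast of the vehicle groups on all 18. Probes were called at a Benjamini-Hochberg adjusted p under 0.05 over all probes. Gene lists were tested with limma's camera at the preset correlation of 0.01, with 1 probe per gene (the highest mean) and a minimum of 5 measured genes, and adjusted over the 39 lists. The lists hold 849 symbols, of which 705 were measured. Camera with an estimated correlation and limma's fry were alternatives. A list's count of passing members is given over all genes and adjusted over the list alone. In totals over lists, a gene that belongs to several lists counts in each.

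Groups, comparisons, lists, alternatives and the rule for named genes were fixed before the data were examined. For each contrast of a dose with vehicle and for the vehicle contrast between tissues, the rule takes, among probes with 1 symbol that passed and whose 3 values all lie beyond the 3 of the other group, the 10 largest rises and 10 largest falls, 1 probe per gene. Where fewer pass, places up to 5 per direction go to the smallest unadjusted p among fully separated probes in the upper 50% by mean. Of each called list it takes the 4 members with the smallest unadjusted p, and it always takes Thrsp, Hr, Klf9, Dio2, Ttr, Cyp1a1, Cyp2b1, Nqo1, Mbp, Gfap, Fos, Igf1, Chrna4 and Ryr2 where present; a further gene of the rule is not reported here. Further genes are members of the fixed lists that passed over all genes or adjusted over the list alone in the comparison described.

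Responses to both doses share their controls, so their correlation across probes was set beside 100 simulations of unchanged groups with the same sharing. Intervals of list medians come from 2000 bootstrap resamples of genes. Alternatives were quantile normalization, median centring, the brighter 50% of probes, eBayes with trend and robust options, array weights, the replicate number as a block, other sets of arrays in the fit, an adjusted p under 0.1, the mean of a gene's probes, and leaving out each replicate. Added after seeing the data were each array's score on the first principal component of the group-centred total brain arrays (45.8% of their variance) as a covariate, pairs of arrays left out together, and a minimum log2 difference of 1 between the tissues. The fits were tested on simulated data made from the means and SDs of the arrays with 100 changed probes per size. There 7 of 146 calls in total brain and 13 of 169 in frontal lobe were false, and 0 calls were made with no change. Noise was drawn independently for each probe, and changes were placed only in the brighter 50%. These counts therefore do not cover variation shared between probes or changes near the floor. For arrays, the number of replicates limits the precision.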

Results

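Messenger RNA was profiled on 18 Illumina rat arrays from the brains of female Wistar pups. Their dams had been injected in the tail with BDE-47, a brominated diphenyl ether of the kind used in flame retardants, or with its vehicle. Each tissue was sampled at 0 (vehicle), 0.002 and 0.2 mg/kg per injection, with 3 pups per group and a single pup per litter. Total brain was taken at postnatal day 10 after 3 injections per dam. Frontal lobe was taken at postnatal day 41 after 6 injections, per its own sample protocol, whereas the series-level design text gives day 10 for both tissues. Tissue, age and injection schedule therefore differ together. Each array gave values for 22523 probes between 7.45 and 15.75 on a log2-like scale. Averaged over the arrays, 57.1% of probes had a mean under 8, near the floor of the scale, and 14.7% had a mean of at least 10. Pairs of arrays of a tissue, over all dose groups, correlated across probes at r between 0.984 and 0.998 in total brain and between 0.981 and 0.997 in frontal lobe. The median SD of a probe within a group was 0.046 in total brain and 0.051 in frontal lobe, and the small number of arrays limits the precision of every mean below.

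The comparison of 0.2 mg/kg with vehicle in the frontal lobe asks how the higher dose affected transcripts at the older age. Among the probes that passed, the ribosomal protein gene Rpl7 rose from 11.72 ± 0.11 to 12.88 ± 0.08 (mean ± SD, log2, n = 3, adjusted p = 0.000894 in limma), and the related Rpl37l1 rose from 10.60 ± 0.13 to 12.05 ± 0.22, a log2 difference of 1.45. Rpl23 rose by 0.72 and Rplp0, a protein of the ribosomal stalk, by 0.34. A probe for Eef1a1, the elongation factor that brings aminoacyl-tRNA to the ribosome, rose by 1.15, but 2 of the 4 other Eef1a1 probes had the opposite sign. Myo5a, a myosin motor that carries organelles into dendritic spines, fell from 11.69 ± 0.26 to 10.40 ± 0.19, and Hpcal4, a neuronal calcium sensor, fell from 11.35 ± 0.40 to 10.11 ± 0.30.

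Among the other probes that passed, Pex5l, a subunit of the HCN channel complex, fell by 0.95, the neuronal polarity kinase Brsk1 by 0.84 and the co-chaperone gene Dnajb14 by 1.14. Slc17a7, which loads glutamate into synaptic vesicles, went from 10.47 ± 0.07 to 9.69 ± 0.20 (log2 difference -0.78, adjusted p = 0.0179). The endocytic adaptor gene Epn1 fell by 0.76, the lipid kinase gene Pi4k2a by 0.81 and Pfkl, which encodes a phosphofructokinase of glycolysis, by 0.81. One Reep5 probe fell by 0.83 while its other probe stood at 0.06. Rises of the same size were seen for the galectin gene Lgals5 (1.21), the RNA-binding protein gene Tsn (1.07), the lysosomal membrane gene Glmp (1.03) and the growth factor binding protein gene Igfbp2 (0.88). Hapln2, which links extracellular matrix at nodes of Ranvier, rose by 0.83, Rasgef1c by 0.75 and Nkx6-2, a transcription factor of oligodendrocytes, by 0.74. For each gene named so far the 3 exposed values lay beyond the 3 control values, which the naming rule required of all but the list members Rpl23 and Rplp0. Rpl7, Rpl37l1, Rpl23 and the Eef1a1 probe passed whichever of the 6 arrays was left out, and Tsn and Nkx6-2 in 5 of 6 such fits. Myo5a, Hpcal4, Slc17a7, Pex5l and Igfbp2 passed in 3 of 6. Full separation fixes the sign in each of these fits.

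**Figure D1:**
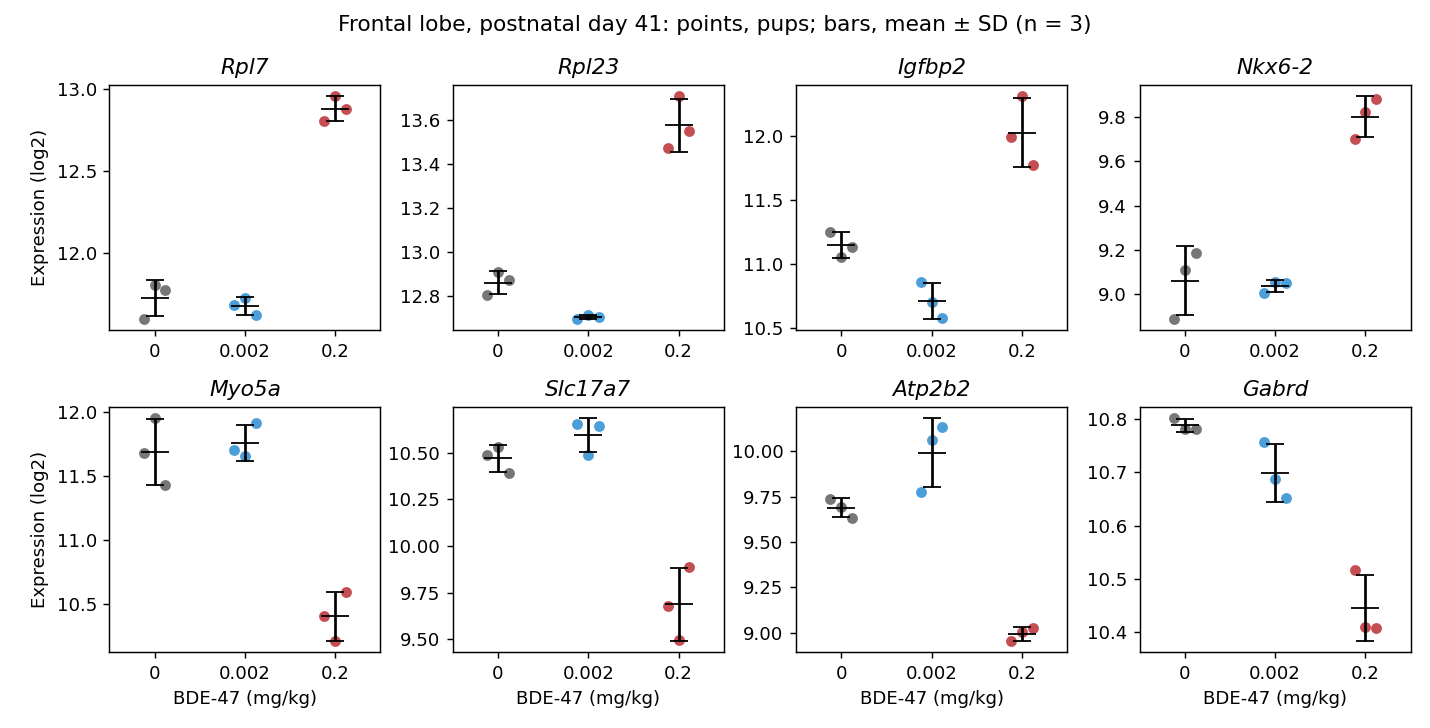
Log2 expression of 8 genes in each frontal lobe array, by dose in mg/kg; points are single pups and bars the mean ± SD of 3. Rpl7 lay at 12.88 ± 0.08 at 0.2 mg/kg against 11.72 ± 0.11 in controls, and Myo5a at 10.40 ± 0.19 against 11.69 ± 0.26.

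In all, 257 of 22523 probes passed, 145 up and 112 down, and 191 of them carried a gene name. Their median absolute log2 difference was 0.44, and 24 reached 1. The farthest changes belonged to probes with no gene name here, ILMN_1362081 at -2.16 and ILMN_1373381 at -2.14, both picked out after their values had been seen. Before adjustment 3375 probes had p under 0.05, and 17.6% of probes had fully separated groups, where chance gives 10%. The count fell to 27, 51, 44 and 120 without control replicate 2, control replicate 1, 0.2 mg/kg replicate 1 and 0.2 mg/kg replicate 2, and grew to 1036 without control replicate 3. The count was 5 in a fit of these 6 arrays alone and 9 without control replicate 1 and 0.2 mg/kg replicate 2 together. It was 1 after adding, as a covariate chosen once the data had been examined, each array's score on the main axis of variation within total brain groups. With that covariate all 257 signs and 0.815 of the median absolute log2 difference were kept, while the median SE went from 0.063 to 0.090. The labels name no chip, so an effect of chip on this count, and on that between the doses, cannot be separated from dose.

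Among 39 gene lists fixed before the data were examined, camera in limma called 11 at this dose, and fry called 0. Of the 10 ways to split these 6 arrays evenly, 3 called at least 11 lists by camera, the real one included, and the highest called 13. Calcium signalling genes shifted down, with 24 of 26 below 0 and a median log2 difference of -0.16 (adjusted p = 4.68e-06; adjusted p = 0.417 with an estimated correlation). Among them Atp2b2, the plasma membrane calcium pump, fell by 0.69 while Prkcb (-0.35) and Plcb1 (-0.82) did not pass; 9 members passed when adjusted over the list alone and 1 over all genes. Synaptic vesicle release genes had a median of -0.18 with 16 of 19 below 0 (adjusted p = 6.26e-05; adjusted p = 0.417 with an estimated correlation). Slc17a7 was the member that passed over all genes, and 8 passed adjusted over the list alone, including Vamp2 (-0.36), Pclo (-0.49) and Snap25 (-0.66). Glutamate receptor genes had a median of -0.18 with 17 of 20 below 0 (adjusted p = 3.42e-05; adjusted p = 0.417 with an estimated correlation), and 6 passed adjusted over the list alone and 0 over all genes, led by Grin2a (-1.08) and Gria3 (-0.80). GABA and glycine receptor genes had a median of -0.14 with 13 of 15 below 0 (adjusted p = 0.00144; adjusted p = 0.417 with an estimated correlation); Gabrd, the delta subunit of extrasynaptic GABA-A receptors, fell by 0.34, and 2 passed adjusted over the list alone.

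Voltage-gated sodium and potassium channel genes had a median of -0.13 (adjusted p = 0.00336; adjusted p = 0.417 with an estimated correlation), with Scn2a at -0.86 and 4 members passing adjusted over the list alone, 0 over all genes. Cortical projection neuron markers had a median of -0.14 (adjusted p = 0.0127; adjusted p = 0.417 with an estimated correlation), with 2 passing adjusted over the list alone, of which Slc17a7 passed over all genes and Neurod6 (-0.58) did not. Immediate early genes, which neuronal activity induces, had a median of -0.20 (adjusted p = 0.0280; adjusted p = 0.608 with an estimated correlation), with Egr1 at -0.52, Fos at -0.38 and Junb at -0.70, and none of the 22 passed by either adjustment. Cytosolic ribosomal protein genes shifted up, 31 of 38 above 0 with a median of 0.17 (adjusted p = 5.54e-06; adjusted p = 0.459 with an estimated correlation); 3 rose over all genes and 9 adjusted over the list alone. Meninges and fibroblast genes had a median of 0.20 (adjusted p = 0.00144; adjusted p = 0.494 with an estimated correlation), with Igfbp2 rising, Igf2 at 0.76 and 4 passing adjusted over the list alone. Interferon and MHC genes had a median of 0.11 (adjusted p = 0.00144; adjusted p = 0.459 with an estimated correlation), with Irf1 at 0.39 and 2 passing adjusted over the list alone, 0 over all genes. Microglia genes had a median of 0.28, 13 of 14 above 0 (adjusted p = 0.00205; adjusted p = 0.494 with an estimated correlation), with Laptm5 at 0.42, Aif1 at 0.42 and P2ry12 at -0.13, and none passed by either adjustment.

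A single exposed array stood out in several of these groups. Relative to the mean of the 9 frontal lobe arrays, 0.2 mg/kg replicate 2 averaged 0.47 for microglia genes against -0.00 and 0.09 in the other exposed arrays, 0.44 for meninges and fibroblast genes against 0.23 and 0.07, 0.27 for ribosomal protein genes against 0.05 and 0.18, and -0.32 for synaptic vesicle genes against -0.12 and -0.11. Among controls, replicate 3 averaged -0.30 for meninges and fibroblast genes against 0.14 and 0.06. Without 0.2 mg/kg replicate 2 the number of lists called was 7, and without 0.2 mg/kg replicate 1 it was 17. With the axis score as a covariate it was 3, of which the meninges and fibroblast list was the one shared with the 11.

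The other 28 lists were not called in this comparison (adjusted p from 0.0539 to 0.970, medians from -0.10 to 0.12). Across them 4 members rose, Igfbp2 of the growth factor list among them, and 3 fell over all genes, and 16 and 17 did so adjusted over the list alone. In 8 of the 28 the median, mean and test differed in sign: thyroid hormone axis, xenobiotic metabolism, choroid plexus, cerebellum and hindbrain, striatum, inhibitory interneuron, oxidative phosphorylation, and insulin-like growth factor and mTOR. Oxidative stress defence (median 0.04) held a fall of Keap1, the repressor of the Nrf2 response, by 0.48 and a rise of ferritin heavy chain, Fth1, by 0.24. Fatty acid and glucose metabolism (-0.08) held a fall of the mitochondrial regulator Ppargc1a by 0.35 and a rise of Gapdh by 0.40, developing neuron and axon growth (-0.05) a fall of Dpysl3 by 0.51, and apoptosis (0.02) a rise of Casp12 by 0.20. No member passed over all genes in the lists for cholinergic (-0.04), myelin and mature oligodendrocyte (0.12), red blood cell (0.06), hypothalamic neuropeptide (0.05), ependyma and cilia (0.04), circadian clock (-0.08), oligodendrocyte precursor (-0.10), cholesterol synthesis (-0.09), endothelial and mural (-0.06), cell cycle (0.03), glucocorticoid response (-0.02), monoaminergic (-0.01), pituitary hormone (0.02), heat shock and ER stress (0.04), astrocyte (0.02), or steroid hormone and nuclear receptor genes (0.02).

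Set directly against each other, the frontal lobes at 0.2 and 0.002 mg/kg differed in more probes than either dose did from vehicle. Rpl7 rose by 1.21, Rpl23 by 0.87 and Rpl24 by 0.85 at the higher dose, Igfbp2 rose by 1.31 and Igf2, a fetal growth factor, by 0.94. Atp2b2 fell by 1.00, Slc17a7 by 0.91, Rims1, a scaffold of the presynaptic active zone, by 1.17, Snap25 by 0.73 and the NMDA receptor subunit Grin2a by 1.18. The counts were 646 probes, 321 up and 325 down, with 4218 at p under 0.05 before adjustment. Of the 257 probes above, 209 passed here as well, all in the same direction, while Rpl24, Igf2, Rims1, Snap25 and Grin2a had not passed against vehicle. Both comparisons use the same 0.2 mg/kg arrays. The fold changes correlated across probes at 0.83, against a mean of 0.50 in simulations of unchanged groups with the same shared arrays. The spread of those simulations was not recorded. For simulated frontal lobe responses to both doses, which also share 1 group, the central 95% of correlations lay between -0.50 and 0.87. Thus 0.83 is not shown to exceed what sharing gives. The count fell to 37, 28 and 65 without 0.002 mg/kg replicates 1, 2 and 3, to 407 without 0.2 mg/kg replicate 1 and to 216 without 0.2 mg/kg replicate 2.

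By list, this dose-to-dose comparison called 14. Ribosomal protein genes were higher at 0.2 mg/kg, with 8 of 38 rising over all genes and 14 adjusted over the list alone beside 1 that fell there (adjusted p = 2.65e-09). Higher too were meninges and fibroblast (3 rose, 7 adjusted over the list alone), oxidative phosphorylation (3 rose and Sdha fell; 8 up and 3 down adjusted over the list alone), interferon and MHC (Irf1 rose by 0.36; 3 adjusted over the list alone), microglia (0 and 0), red blood cell (0 over all genes, 6 adjusted over the list alone), ependyma and cilia (0 and 3) and hypothalamic neuropeptide genes (0 and 0). Lower were synaptic vesicle release (7 fell, 12 adjusted over the list alone), calcium signalling (5 fell; 9 down and 1 up adjusted over the list alone), GABA and glycine receptor (Gabrd fell by 0.25; 8), glutamate receptor (Grin2a; 5), cortical projection neuron (Slc17a7; 5) and voltage-gated channel genes (0; 1). Across the 14, adjusted p ran from 2.65e-09 to 0.0319 with the preset correlation, and adjusted p = 0.409 to adjusted p = 0.580 with an estimated correlation, so no call held there. Fry, which asks whether a list's genes move one way without comparing them with other genes, called 8 lists, 7 of them among these 14 in the same direction.

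At 0.002 mg/kg against vehicle in the frontal lobe no gene passed. The nearest named probes were Ccl19, a chemokine, at 8.68 ± 0.06 against 9.08 ± 0.06 in controls (-0.40), the mitochondrial ribosomal gene Mrpl4 (-0.25), Adprh (-0.19), Tbxa2r (-0.13) and one of 2 Bccip probes (-0.21, the other with the opposite sign), and in the other direction Lzts1 at 11.99 ± 0.04 against 11.57 ± 0.10 (0.42), Phc3 (0.27), Lhfpl6 (0.20), Ralgds (0.19) and Zfp667 (0.18), all with adjusted p = 0.910. Limma called 0 probes, with 1151 at p under 0.05 before adjustment and 12.8% fully separated against 10% by chance. Of the lists, 4 shifted down: oxidative phosphorylation, 31 of 34 below 0 (median -0.09, adjusted p = 3.65e-05), meninges and fibroblast, 16 of 16 (-0.18, adjusted p = 0.000323), ribosomal protein, 28 of 38 (-0.10, adjusted p = 0.000723), and endothelial and mural genes, 13 of 13 (-0.10, adjusted p = 0.00106). Examples are Cox8a of the respiratory chain (-0.21), the ribosomal Rps14 (-0.17), the angiopoietin receptor Tek (-0.19) and Igfbp2 (-0.43). Myelin and mature oligodendrocyte genes shifted up with a median of 0.12 (adjusted p = 0.0406 in camera), for example Cldn11 at 0.40. This call was kept in 2 of 6 fits with a compared array left out, and each of the 4 downward calls in 5 of 6. For all 5 lists adjusted p = 0.765 with an estimated correlation, and 0 members passed over all genes or adjusted over the list alone. Without control replicate 3, 3 lists were called, all down, of which 2 were among the 5. That array was low in meninges and endothelial genes (-0.30 and -0.13 relative to the mean), which works against a fall of those lists.

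In total brain at 0.002 mg/kg no gene passed either. Arpin, an inhibitor of the Arp2/3 actin nucleator, came nearest at 9.68 ± 0.02 against 10.04 ± 0.06 in controls (-0.36, adjusted p = 0.0534). Next were the adhesion receptor Adgrb1 (0.48), Mtbp (0.15), Myl12b (0.58), Acsl5 (0.19) and Ybx3 (0.48), and below controls Coq3 of ubiquinone synthesis (-0.60), Mrps26 (-0.60), Rps29 (-0.41) and one of 2 Cdc40 probes (-0.20, the other 0.31). Limma called 0 probes, with 1468 at p under 0.05 before adjustment and 13.0% separated against 10% by chance. Without 0.002 mg/kg replicate 2 the count was 1.

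Camera called 12 lists in total brain at this dose. Ribosomal protein genes were lower in 37 of 38 cases (median -0.17, adjusted p = 7.53e-08), with Rps15 at -0.48 and Rpl23 at -0.30. Also down were oxidative phosphorylation (median -0.08, adjusted p = 0.0313), developing neuron and axon growth (-0.09), cell cycle (-0.07) and interferon and MHC genes (-0.02), these last 3 at adjusted p = 0.0448. Up were glutamate receptor (17 of 20 above 0, median 0.13, adjusted p = 0.000373; Grin1 at 0.29), synaptic vesicle release (0.08, adjusted p = 0.0174; Snap25 at 0.50), myelin and mature oligodendrocyte (0.13, adjusted p = 0.0174; Mobp at 0.55), astrocyte (0.21, adjusted p = 0.0305; Gja1 at 0.22), voltage-gated channel (0.05, adjusted p = 0.0346; Scn1a at 0.66), cerebellum and hindbrain (0.10, adjusted p = 0.0362; Hoxb5 at 1.10) and circadian clock genes (0.03, adjusted p = 0.0448; Per1 at 0.21). With an estimated correlation the 12 gave adjusted p = 0.607 to adjusted p = 0.703, and over all genes 0 members passed, against Grm8 and Vamp2 adjusted over the list alone. Relative to the mean of the 9 arrays, ribosomal protein genes averaged 0.21 in control replicate 3 and -0.21 in 0.002 mg/kg replicate 2, and synaptic vesicle genes -0.14 and 0.14. The number of lists called was 3 without control replicate 3, 6 without control replicate 1, 6 without 0.002 mg/kg replicate 2, and 3 without control replicate 3 and 0.002 mg/kg replicate 2 together.

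Total brain at 0.2 mg/kg gave 0 probes in limma, with 972 at p under 0.05 before adjustment and 10.1% separated against 10% by chance. Arpin again lay lowest in p (9.68 ± 0.03 against 10.04 ± 0.06, -0.35, adjusted p = 0.118). The same control arrays serve both doses, so this is not an independent repeat. Plekhf2 (-0.92), Snx16 (-0.35), Cd83 (-0.23), Zdhhc6 (-0.18), Tspan9 (0.21), the lysosomal sialidase Neu1 (0.20), Abcg3l2 (0.12), Cox15 (0.11) and Pip5k1b (0.11) followed, none passing. Camera called 13 lists. Up were myelin and mature oligodendrocyte (median 0.17; Mobp at 0.53, Mag at 0.20), red blood cell (0.08; the globin gene Hbb-b1 at 1.05, Ahsp at 0.59), cerebellum and hindbrain (0.11; Hoxb8 at 0.51), glutamate receptor (0.06; Gria4 at 0.19) and synaptic vesicle release genes (0.09; Syp at 0.21), all at adjusted p = 0.00415. Astrocyte genes followed at adjusted p = 0.00763 (0.09; Slc1a2 at 0.18), then thyroid hormone axis (0.03), choroid plexus (0.02; Ttr at 0.43) and voltage-gated channel genes (0.05) at adjusted p = 0.0471. Down were developing neuron and axon growth (-0.05, adjusted p = 0.0294; Sox4 at -0.32), and cell cycle (-0.03; Aurkb at -0.17), ribosomal protein (-0.03; Rpl23 at -0.24) and interferon and MHC genes (-0.03; Psmb8 at -0.27) at adjusted p = 0.0471. With an estimated correlation the 13 gave adjusted p = 0.513 to adjusted p = 0.715, and 0 members passed over all genes against Hoxb8 adjusted over the list alone. The number called was 4 without control replicate 3 and 4 without 0.2 mg/kg replicate 2, and after quantile normalization the thyroid hormone axis and choroid plexus calls were lost.

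Between both total brain doses limma called 0 probes (1321 at p under 0.05 before adjustment). Ribosomal protein genes were higher at 0.2 than at 0.002 mg/kg in 33 of 38 cases (median 0.09, adjusted p = 0.00101; adjusted p = 0.990 with an estimated correlation), and circadian clock genes were lower in 12 of 13 (median -0.04, adjusted p = 0.0161; adjusted p = 0.477 with an estimated correlation), with 0 members passing over all genes or adjusted over the list alone. In simulated data for the comparison of 0.2 mg/kg with control, limma recovered 58% of probes changed by 0.5 log2 and 81% of those changed by 1 in total brain. In frontal lobe it recovered 64% and 92%. The simulated noise was independent between probes and only brighter probes were changed. Recovery in the real arrays, with shared variation and many probes near the floor, may therefore be lower.

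**Figure D2:**
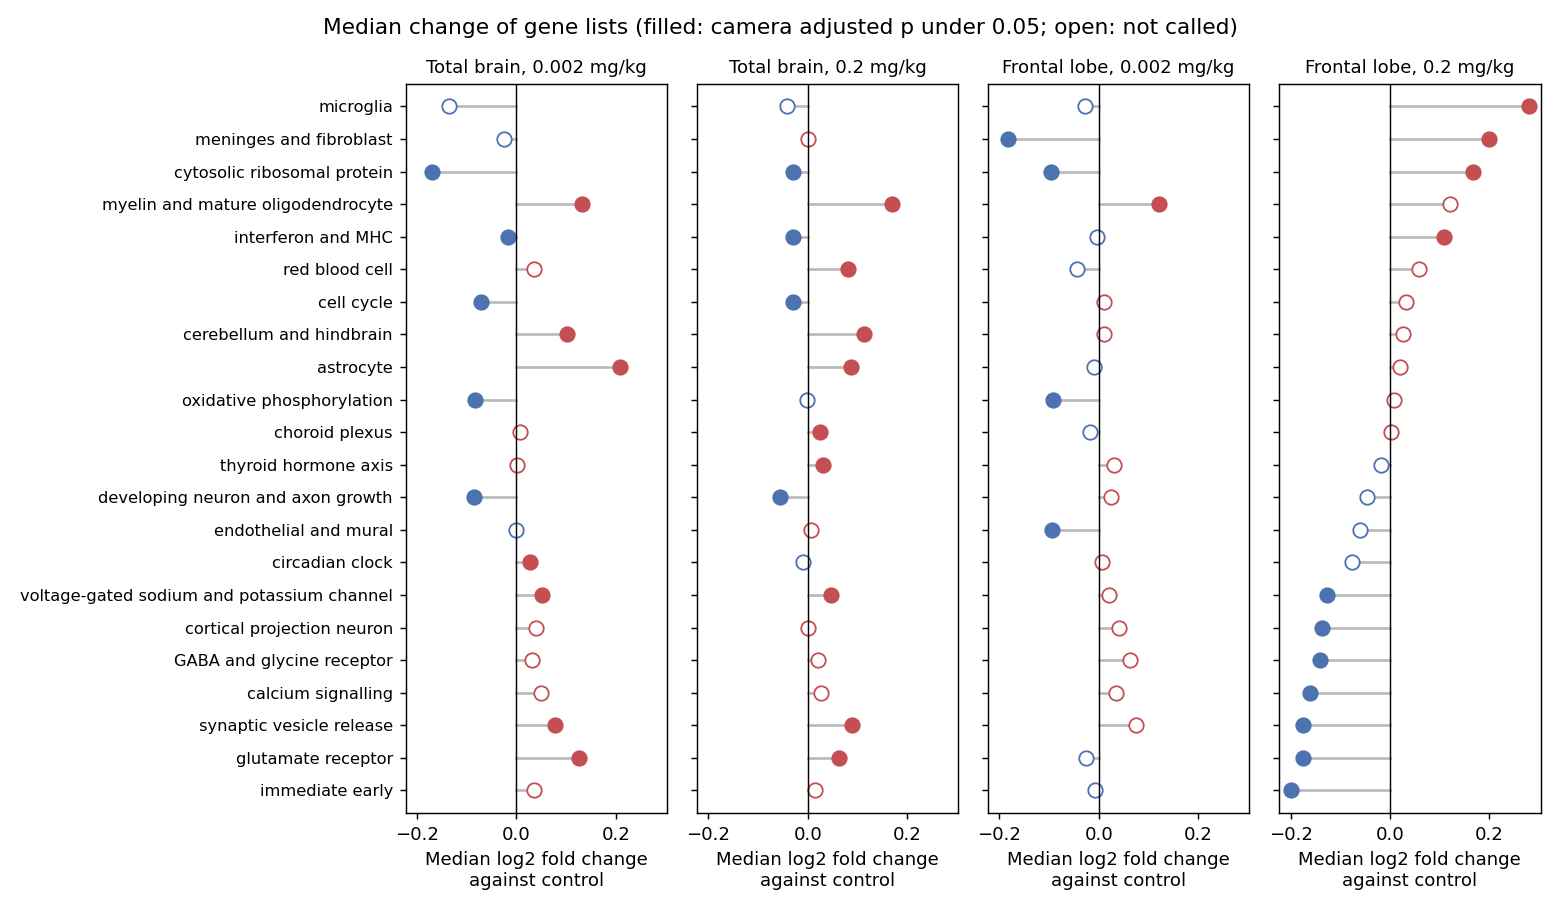
Median log2 difference of 22 gene lists in each comparison of a dose with vehicle, filled where camera called the list at the preset correlation, calls that did not hold with an estimated correlation. Ribosomal protein genes had medians of -0.17 and -0.03 in total brain and -0.10 and 0.17 in frontal lobe at 0.002 and 0.2 mg/kg, and synaptic vesicle release genes 0.18 below control in frontal lobe at 0.2 mg/kg.

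Across all probes the responses to both doses correlated at r = 0.50 in total brain and 0.18 in frontal lobe. Unchanged groups simulated against shared controls gave means of 0.49 (central 95% of simulations from -0.68 to 0.95) and 0.41 (from -0.50 to 0.87). The covariances were 0.00399 in total brain against 0.00427 simulated, and 0.00317 in frontal lobe against 0.00345 simulated, a difference of -0.00028 in each. Genes are not independent replicates. The 3 controls of each tissue were not split between the doses, which would have left 1 dose with 1 control. The frontal lobe and total brain responses to 0.2 mg/kg, which share no array, correlated at -0.06.

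Whether the response itself differed between the tissues was tested as an interaction over all 18 arrays. At 0.2 mg/kg 46 probes passed, 21 with a more positive and 25 with a more negative response in frontal lobe, and 43 of them were among the 257. Rpl37l1 responded by 1.72 more in frontal lobe, one of 5 Eef1a1 probes by 1.54, Tsn by 1.44, Rpl7 by 1.36 (adjusted p = 0.00016) and Rpl23 by 0.96. The difference was -1.32 for Myo5a, -0.95 for Slc17a7, -0.87 for Pfkl, -0.84 for Pex5l and -0.70 for Atp2b2. The interaction contains the frontal lobe contrast, and the fold changes of both correlated across probes at 0.92. Simulations of unchanged groups gave a mean of 0.67, with a spread that was not recorded. At 0.002 mg/kg limma called 0 probes, with 1108 at p under 0.05 before adjustment. The count at 0.2 mg/kg lay between 14, without total brain 0.2 mg/kg replicate 1, and 370, without frontal lobe control replicate 3.

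The vehicle groups of both tissues describe what region, age and schedule amount to together. The tissues stand in a single table but seem to have been normalized separately, since array medians were 7.88 to 7.89 in total brain and 7.83 to 7.84 in frontal lobe. Genes of dividing and immature cells were lower in the frontal lobe at day 41. All 21 cell cycle genes fell (median -0.96, adjusted p = 6.43e-14; adjusted p = 0.00859 with an estimated correlation), among them Cdk1 (-2.53) and Ccna2 (-1.35), and 18 of 20 developing neuron and axon growth genes fell (median -0.87), led by the tubulin gene Tubb2b, from 13.60 ± 0.04 to 9.80 ± 0.13. The proneural factor Neurod1 (-3.21), Igfbpl1 (-3.42), the chromatin protein gene Hmgb2 (-2.79), Nrep (-2.57) and Dynlt1 (-2.59) fell too, as did the hypothalamic peptide genes Pmch (-2.72) and Nts (-2.56) and the choroid plexus transthyretin gene Ttr (-4.24). Higher in the frontal lobe were the plasma protein gene Alb (3.40, with an SD of 2.05 among the frontal controls), Tnnc2 (2.88), Ptgs2 (2.77), the myelin gene Mal (2.68), Hpcal4 (2.51), the immediate early gene Egr1 (2.49), Ddn of dendrites (2.17), Cyp11b1 (2.14), S100b of glia (2.08) and Cabp1 (2.05).

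Limma called 11866 probes between the tissues, 2030 higher and 9836 lower in frontal lobe, so that 17.1% were higher, and 546 of them (276 higher, 270 lower) differed by at least 1. After quantile normalization of all arrays the count was 5226 with 47.0% higher, after median centring 5828 with 39.6% higher, and among the brighter 50% of probes 5438 with 34.8% higher. Camera called 24 lists, and 8 held with an estimated correlation: cell cycle, voltage-gated channel (12 rose; adjusted p = 0.0182), synaptic vesicle release (13 rose and 2 fell; adjusted p = 0.0379), developing neuron and axon growth (adjusted p = 0.0379), cortical projection neuron (6 rose; adjusted p = 0.0379), astrocyte (8 rose; adjusted p = 0.0415), circadian clock (6 rose, 1 fell; adjusted p = 0.0415) and fatty acid and glucose metabolism genes (10 rose, 8 fell; adjusted p = 0.0415). The 16 others, at adjusted p = 0.188 to adjusted p = 0.481 with an estimated correlation, were up for myelin and mature oligodendrocyte (8 rose, 4 fell), microglia (4 rose), calcium signalling (11 rose, 3 fell), immediate early (11 rose, 2 fell), glutamate receptor (8 rose, 4 fell), GABA and glycine receptor (5 rose, 4 fell), thyroid hormone axis (6 rose, 4 fell), inhibitory interneuron (5 rose, 3 fell), glucocorticoid response (6 rose, 1 fell) and oxidative phosphorylation genes (9 rose, 5 fell). They were down for oligodendrocyte precursor (6 fell), choroid plexus (11 fell, 1 rose), ependyma and cilia (9 fell, 1 rose), hypothalamic neuropeptide (10 fell, 2 rose), cerebellum and hindbrain (11 fell, 1 rose) and ribosomal protein genes (24 fell, 1 rose). Adjusted over the list alone, members of the 24 lists gave 135 rises and 159 falls, against 135 and 151 over all genes. The median, mean and test differed in sign for thyroid hormone axis, inhibitory interneuron, glucocorticoid response and oxidative phosphorylation, and after quantile normalization thyroid hormone axis, inhibitory interneuron, oxidative phosphorylation and GABA and glycine receptor genes were no longer called while cholesterol synthesis and apoptosis genes were, both down. The 15 lists not called gave adjusted p from 0.0793 to 0.968.

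Changes at 0.2 mg/kg in the frontal lobe ran against this tissue difference. Hpcal4, 2.51 higher in frontal lobe than in total brain controls, fell by 1.25 with exposure, Slc17a7 (1.16 higher) fell by 0.78, and Gabrd (1.74 higher) fell by 0.34. Rpl7, 1.27 lower on the log2 scale in frontal lobe (-1.27), rose by 1.16. Of the 257 probes, 204 also differed between the tissues, and 188 of these, 92.2%, had opposite signs. Over all 22523 probes 11866 differed between the tissues, 9836 of them lower in frontal lobe. Unrelated calls would thus leave about 62 probes called in both with the same sign, against 16 here. Both contrasts use the frontal lobe controls, with opposite signs. Across probes r was -0.47, where simulation without any effect gave a mean of -0.12 (central 95% of simulations from -0.34 to 0.11). With the 0.002 mg/kg frontal lobe arrays in place of the controls in the tissue contrast, no array was shared, r was -0.40, and 176 of 195 probes called in both were opposite.

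**Figure D3:**
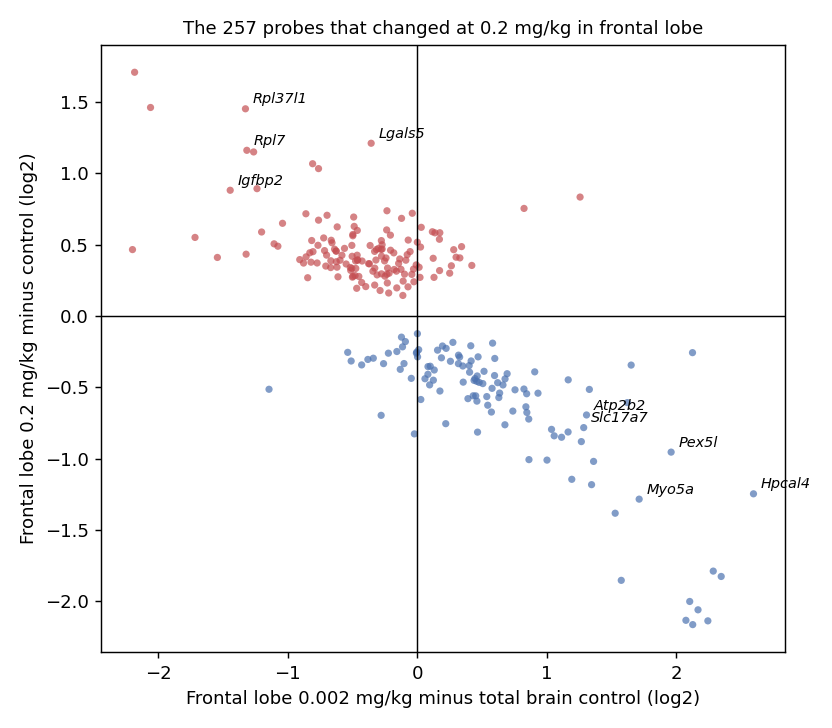
Log2 difference between 0.2 mg/kg and control frontal lobe for the 257 passing probes, against the log2 difference between 0.002 mg/kg frontal lobe and control total brain, which shares no array with it. Of the 195 probes that also passed on the horizontal axis, 176 have opposite signs on the axes.

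Genes chosen in advance for thyroid, xenobiotic, glial and activity readouts did not pass in any comparison of a dose with vehicle. No passing change was found at either dose in either tissue for Thrsp, Hr, Klf9 and Dio2, which respond to thyroid hormone or activate it, for the dioxin-inducible Cyp1a1, for Mbp of myelin, Gfap of astrocytes, Fos, the nicotinic receptor subunit Chrna4 or the ryanodine receptor Ryr2. In frontal lobe at 0.2 mg/kg Cyp1a1 was at 7.61 ± 0.03 against 7.59 ± 0.01 in controls, near the floor, and Klf9 at 13.09 ± 0.02 against 13.11 ± 0.11. Nqo1, a quinone reductase under Nrf2 control, was at 10.21 ± 0.30 against 9.63 ± 0.05 (0.58, adjusted p = 0.0844). Mbp was at 11.38 ± 0.30 against 10.80 ± 0.39, Gfap at 12.71 ± 0.73 against 12.23 ± 0.28, and the brightest Ryr2 probe differed by -0.27 (adjusted p = 0.0732), with 2 of its 3 other probes of opposite sign, though between the doses it fell by 0.38 (adjusted p = 0.0223) and a further Ryr2 probe fell by 0.26 (adjusted p = 0.0311). In total brain at 0.2 mg/kg Ttr was at 13.61 ± 0.16 against 13.18 ± 0.15 and Thrsp at 8.77 ± 0.19 against 8.97 ± 0.10. Cyp2b1 and Igf1 had no named probe here.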

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

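The test of a lower neuron share, the axis covariate and the fits without pairs of arrays were chosen after the results were seen. Genes and lists are given here because they were called for an interaction term in limma between dose and tissue. Tissue, age, injection schedule and any chip effect cannot be separated in that term. Groups of 3 are too small for a test of single samples.

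At 0.2 mg/kg 46 probes passed for the interaction. The response was more positive in frontal lobe for the ribosomal protein genes Rpl37l1 (1.72 on the log2 scale), Rpl7 (1.36) and Rpl23 (0.96) and for a probe of the elongation factor Eef1a1 (1.54), whose other probes differed by between -0.04 and 0.06 and did not pass. The RNA-binding protein gene Tsn (1.44) and the oligodendrocyte factor Nkx6-2 (0.68) did so too. The difference was -1.32 for the myosin motor Myo5a, -0.95 for the vesicular glutamate transporter Slc17a7, -0.87 for the phosphofructokinase Pfkl, -0.84 for the channel subunit Pex5l and -0.70 for the calcium pump Atp2b2. The count was 22 without total brain control replicate 2 or 3, 14, 16 and 25 without total brain 0.2 mg/kg replicates 1, 2 and 3, 26 and 370 without frontal lobe control replicates 2 and 3, and 30 and 23 without frontal lobe 0.2 mg/kg replicates 1 and 2.

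By list, the responses to 0.2 mg/kg differed for 13, with frontal lobe lower for synaptic vesicle release (median difference -0.26), glutamate receptor (-0.26), calcium signalling (-0.19), voltage-gated sodium and potassium channel (-0.16), GABA and glycine receptor (-0.16), cortical projection neuron (-0.17), immediate early (-0.23) and fatty acid and glucose metabolism genes (-0.071). It was higher for ribosomal protein (0.20), interferon and MHC (0.12), microglia (0.35), meninges and fibroblast (0.24) and cell cycle genes (0.069). At 0.002 mg/kg glutamate receptor genes differed by -0.12 (adjusted p = 0.0189; adjusted p = 0.797 with an estimated correlation). For the 13 lists adjusted p was at most 0.0390, and adjusted p = 0.256 to adjusted p = 0.581 with an estimated correlation, so none held there, while fry called 5 lists, 4 of them among the 13. Over all genes 2 members had a higher and 3 a lower response, against 13 and 31 adjusted over the list alone. Among the 3, Slc17a7 counts in both the cortical projection neuron and the synaptic vesicle release list.

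Of 100 splits of the arrays into groups of the same sizes, 3 gave at least the 46 probes of the interaction at 0.2 mg/kg, the real one included, and the highest other split called 196. That is several times the real count and points to a structure of the samples: the 10 other splits that kept the frontal lobe groups gave 7 to 196 and the 89 that mixed them at most 30. The count thus follows the frontal lobe difference. Among the 11 splits that kept those groups, the real one included, 3 gave at least 46, so chance is not excluded as the source of a difference between the tissues' responses. At 0.002 mg/kg the real count was 0, which each of the 100 splits reaches by construction (the highest gave 4), so the splits decide nothing there.

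A lower share of neurons in the exposed samples was considered for the 257 probes called at 0.2 mg/kg in frontal lobe. With the mix of the other cell types fixed, it would raise all their markers alike. Yet 2 pairs of the 5 non-neuronal lists moved apart: microglia (median 0.28, 95% interval 0.11 to 0.44) and meninges and fibroblast genes (0.20, 0.09 to 0.42) each against endothelial and mural genes (-0.06, -0.10 to 0.04). This argues against a lower neuron share as the whole cause only if that mix was fixed and the lists respond alike on this scale. Neither condition was tested. These intervals resample genes only, and single arrays move the medians: microglia was at 0.14 and meninges and fibroblast at 0.08 without 0.2 mg/kg replicate 2, and the latter at 0.05 without control replicate 3, but 1 to 4 pairs stood apart in each of the 6 fits with an array left out. A shared axis of variation between arrays, which total brain arrays also show within their groups, may contribute, since loadings on it correlated with the fold changes over these probes at r = 0.81. With its score as a covariate 0.815 (jackknife SE 0.071) of the median absolute log2 difference was left, 0.44 before and 0.36 after, all 257 signs were kept, the median SE went from 0.063 to 0.090, and 1 call was left; the parts of the smaller difference, the larger SE and the lost degree of freedom in this were not separated. The score and the groups correlated at 0.84, so axis and dose cannot be told apart, and a response to BDE-47 stays open.

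The gene lists called in total brain, where no probe was called, were set against 2 arrays that stand apart, control replicate 3 and 0.002 mg/kg replicate 2. Without both, 3 lists were called at 0.002 mg/kg in place of 12, with 1 in common. The pair was chosen from these data, no other pair was left out, and fewer arrays can themselves lower the count. The fall therefore cannot be credited to these arrays in particular. Without control replicate 3 alone the count was 3, without control replicate 1 it was 6 and without 0.002 mg/kg replicate 2 it was 6. At 0.2 mg/kg 6 were called in place of 13, with 4 in common, and 4 without control replicate 3 and 4 without 0.2 mg/kg replicate 2. Of the 2 arrays only control replicate 3 enters that contrast, the other adding to the estimate of the spread alone, so leaving out both decides nothing at that dose. A response of the pups to BDE-47 stays open at either dose.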

How the results depend on the processing

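The axis covariate, arrays left out together and the minimum difference between tissues were chosen after seeing the data; the cause of each change was not tested unless stated.

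In frontal lobe at 0.2 mg/kg, 257 probes became 558 among the brighter 50% of probes (fewer probes tested), 487 with eBayes trend and robust, 633 with all 18 arrays, 811 at adjusted p under 0.1, 5 with only the arrays of the groups compared, 9 without control replicate 1 and 0.2 mg/kg replicate 2 together, and 1 with the axis score as covariate. Between the doses 646 became 1182 in the brighter 50%, 1211 with trend and robust, 1066 with array weights, 1122 with all 18 arrays and 1624 at adjusted p under 0.1. With the replicate number as a block (replicate block) they were 43 and 65. Deviations of same-numbered frontal lobe arrays correlated between -0.25 and 0.11 (1 of 9 pairs over 0.1), with a median of -0.15 against 0.02 for other pairs. The numbers thus do not seem to pair the frontal lobe arrays. In total brain they correlated between -0.29 and 0.44 (6 of 9 over 0.1), with a median of 0.18 against -0.12 for other pairs (6 of 18 over 0.1). Whether the numbers pair the total brain arrays stays open. The block moved no other probe or list count by over 1.5 times. The interaction at 0.2 mg/kg, 46 probes, became 102 in the brighter 50%, 87 with trend and robust, 79 with array weights and 155 at adjusted p under 0.1.

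Leaving out 1 array gave 27 (without control replicate 2) to 1036 (control replicate 3) at 0.2 mg/kg in frontal lobe, with 51 without control replicate 1, 44 without 0.2 mg/kg replicate 1 and 120 without replicate 2. Between the doses it gave 28 (0.002 mg/kg replicate 2) to 823, with 37 and 65 without 0.002 mg/kg replicates 1 and 3 and 407 and 216 without 0.2 mg/kg replicates 1 and 2. The interaction at 0.2 mg/kg gave 14 (total brain 0.2 mg/kg replicate 1) to 370 (frontal lobe control replicate 3), with 22 without total brain control replicate 2 or 3, 16 and 25 without total brain 0.2 mg/kg replicates 2 and 3, 26 without frontal lobe control replicate 2 and 30 and 23 without frontal lobe 0.2 mg/kg replicates 1 and 2; at 0.002 mg/kg it gave 0 to 1 (total brain 0.002 mg/kg replicate 2 or frontal lobe control replicate 3).

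Where limma called 0 probes (unadjusted counts of 1468, 972, 1321 and 1151), total brain at 0.002 mg/kg gave 1 in the brighter 50%, 3 with trend and robust, 2 with array weights, 1 with all 18 arrays, 2 at adjusted p under 0.1, 1 without control replicate 3 and 0.002 mg/kg replicate 2 together, and 0 to 1 with single arrays left out (1 without 0.002 mg/kg replicate 2). At 0.2 mg/kg it gave 2 with trend and robust, 2 without those arrays together, and 0 to 1 (without 0.2 mg/kg replicate 3). Between the total brain doses it gave 2 with trend and robust and 0 to 1 (without 0.002 mg/kg replicate 2). Frontal lobe at 0.002 mg/kg gave 0 in each alternative run.

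Gene lists with an estimated correlation were 0 in each dose comparison with vehicle and 8 of 24 between the tissues. Fry, which asks another question, called 1 in total brain at 0.002 mg/kg, 0 at 0.2 mg/kg, and 0 and 0 in frontal lobe, 1 and 8 between the doses in total brain and frontal lobe, 0 and 5 for the interactions at 0.002 and 0.2 mg/kg, and 32 between the tissues. Without the standing-apart arrays together, 12 became 3 and 13 became 6 in total brain, and 5 became 8 in frontal lobe at 0.002 mg/kg. With the axis score 11 became 3. Leaving out 1 array gave 3 to 14 at 0.002 mg/kg in total brain (3 without control replicate 3, 6 without control replicate 1 or 0.002 mg/kg replicate 2), 4 to 14 at 0.2 mg/kg (4 without control replicate 3 or 0.2 mg/kg replicate 2), 3 to 6 in frontal lobe at 0.002 mg/kg (3 without control replicate 3), 7 to 17 at 0.2 mg/kg (7 without 0.2 mg/kg replicate 2, 17 without replicate 1), and 21 to 24 between the tissues.

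Between the tissues 11866 probes became 5226 with quantile normalization, 5828 with median centring, 5438 in the brighter 50% and 546 with a log2 difference of at least 1, the last by construction. With single arrays left out, the correlations of the responses to both doses ran from 0.22 to 0.64 in total brain and from 0.07 to 0.47 in frontal lobe. Their jackknife SE (0.358 in total brain, 0.356 in frontal lobe) comes from these same fits, so it cannot judge them. Quantile normalization and the brighter 50% of probes moved the correlations by less than that SE. For 361 pairs of a named gene and a comparison, of which 128 had passed, 4883 of 5184 alternative values kept direction and side of the threshold, 167 lost the call, 71 gained it, 63 uncalled ones changed sign, and 0 called ones reversed. In frontal lobe at 0.2 mg/kg, 24 of 70 named genes lost the call with the axis score. There 22 lost it with only the arrays of the groups compared, and 21 without the 2 arrays together. Where the naming rule required full separation, leaving out an array cannot reverse a sign. Arrays have no depth; 57.1% of probes had a mean under 8, where signal over background limits what can be seen.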

Other observations

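The test of a less mature frontal lobe was chosen after the result was seen, as was the axis covariate.

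Some genes made mainly in choroid plexus, liver or pituitary varied widely between frontal lobe arrays. Ttr, the thyroid hormone carrier made by choroid plexus, was at 10.71 in control replicate 1 and at most 8.56 in the other frontal lobes, and Alb, the plasma albumin gene, at 13.99 in that array and at most 10.66 in the others. Prl, the pituitary prolactin gene, was at 13.78 in 0.002 mg/kg replicate 3, 11.56 in 0.002 mg/kg replicate 1 and 10.01 in 0.2 mg/kg replicate 1, and between 8.17 and 9.01 in the others. Pomc, the pituitary and hypothalamic precursor of ACTH, was at 8.91, 10.43 and 9.67 at 0.2 mg/kg and at 8.79, 9.10 and 8.81 at 0.002 mg/kg, all above the 8.41 to 8.63 of controls, and did not pass in limma (adjusted p = 0.137 at 0.2 mg/kg and 0.921 at 0.002 mg/kg). In total brain the highest values were 13.74 for Ttr, 8.41 for Alb, 7.91 for Prl and 8.62 for Pomc. These genes were singled out after their values were seen.

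Changes at 0.2 mg/kg in frontal lobe ran against the difference between frontal lobe and total brain controls. The frontal lobe controls shared by both contrasts are argued against as the whole cause: with the 0.002 mg/kg arrays in their place r across probes was -0.40 (jackknife SE 0.099), and between -0.43 and -0.33 with single arrays left out. A less mature frontal lobe at 0.2 mg/kg would raise developing neuron and axon growth genes by 0.19 at the slope of all probes (-0.20). Their median was -0.046 (95% interval -0.19 to 0.03, 20 genes), below even 0.093 at 0.5 of that size. The interval resamples genes only and no array was left out, so it does not cover the spread between pups. These 20 genes did not show the predicted rise, which does not exclude lower maturity. A shared axis of variation between arrays may contribute, since r was -0.13 with its score as a covariate, but score and dose are correlated and cannot be told apart. A response of the frontal lobe to dose stays open.

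For comparisons of 3 arrays with 3, the 10 possible splits are too few for a share under 0.05. In total brain the real probe count was 0 and the highest of the other splits 1 at 0.002 mg/kg, and 0 and 0 at 0.2 mg/kg and between the doses, counts of 0 that all 10 splits reach by construction. In frontal lobe the probe counts were 0 and 0 at 0.002 mg/kg (10 of 10, again by construction), 257 and 1 at 0.2 mg/kg (1 of 10), and 646 and 5 between the doses (1 of 10). Between the tissues they were 11866 and 0 (1 of 10). List counts were 12 real and 13 highest other in total brain at 0.002 mg/kg (2 of 10), 13 and 12 at 0.2 mg/kg (1 of 10), 5 and 7 in frontal lobe at 0.002 mg/kg (6 of 10), 11 and 13 at 0.2 mg/kg (3 of 10), and 24 and 19 between the tissues (1 of 10).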
